A study of Homo sapiens with 4 samples.

How the data were processed

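Gene expression was measured on 4 two-colour spotted cDNA arrays of EJM, an established human multiple myeloma cell line (multiple myeloma is a cancer of antibody-secreting plasma cells). The cells carried a doxycycline-inducible super-repressor form of IκBα, the inhibitor that holds the NF-κB transcription factors in the cytoplasm, and a super-repressor is a form that resists signal-induced breakdown. Per the labels' protocols, cells were treated with 20 µg/ml doxycycline at 37 °C for 1, 2, 3 or 4 days, and 50 µg of total RNA was reverse-transcribed with each dye. On every array the induced cells were labelled with Cy5 and the uninduced control with Cy3, with no dye swap in the labels. The control has the same description on all 4 arrays, and whether it was 1 RNA preparation is not given in the sources used here.

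The deposited values are log ratios of the channels of each array, used here as log2 of Cy5 over Cy3 (induced over uninduced). The deposited values do not state the direction of the ratio. It was taken from the dyes named in the labels as channel 2 (Cy5) over channel 1 (Cy3), and the opposite orientation would turn every sign given here. The log base is not stated: base 10 is excluded by a largest value of 7.26, which would exceed the range of a 16-bit scanner, base 2 is taken, and the natural log is not excluded. The tests do not depend on the base, while every fold does. The array medians lay between -0.068 and 0.004, so the arrays were centred near 0. The background correction, the normalization method, the spot filter and the meaning of a missing value are not given in the sources used here. No spot intensities were used here, so no filter on dim spots could be tried.

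The table listed 15246 probes. A single gene symbol was given for 10169 probes, several for 4, and 5073 probes are unnamed here. Symbols were updated through the Entrez identifier with a RefSeq gene table (GRCh38.p14), which held the identifiers of 10128 probes. That table was used for names only, and no coordinates are given because the build behind the array annotation is not named. Probes of the same symbol were averaged per array and each unnamed probe stayed a feature of its own, which gave 9681 features. A gene's average can rest on different probes on different days where a probe has missing values, and probes of the HLA, globin and ribosomal protein families can cross-hybridise with related transcripts.

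The comparison of induced with uninduced cells was the mean log2 ratio over the 4 arrays against 0, for 7713 features with a value on at least 3 arrays (4212 named genes and 3501 unnamed probes). The day trend was the slope of the log2 ratio on day, for 6427 features with values on all 4 arrays. Both used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given with a mean are the SD over the arrays, and errors given with a slope are the standard error. The 4 arrays are different days and not replicates of a single condition, and nothing says that they came from separate cultures, so the p-values measure only the spread between these arrays. If the control was 1 RNA preparation, the ratio against 0 leaves out the control's own spread. A gene-specific dye bias and any effect of doxycycline itself remain in the mean. A constant dye bias cancels in the slope. Whether the control was kept in parallel for each day is not given in the sources used here. Any difference in time in culture would therefore remain in both the mean and the slope. The number of arrays limits the precision, and each day has 1 array, so the values per day have no replicate check.

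A set of 28 gene lists was fixed before the data were examined. They covered NF-κB targets, a myeloma NF-κB list, NF-κB pathway components, plasma cell and B cell genes, MHC class II and class I, interferon response, G2/M and S phase, inhibitors and promoters of apoptosis, ER stress, the ATF4 amino acid response, p53, MYC and STAT3 targets, sterol synthesis, glycolysis and hypoxia, heat shock, adhesion and migration, ribosomal and mitochondrial ribosomal proteins, the respiratory chain, the proteasome, and markers of T cells, myeloid cells, and red and stromal cells. The myeloma NF-κB list was recalled from published work on this disease and may have been chosen on arrays like these, so it is not independent evidence. TNFAIP3, BIRC3, NFKB2, RELB and NFKBIE are in both this list and the list of NF-κB targets. NFKBIA, which encodes IκBα, was kept out of every list because the transgene is a form of it. Lists with at least 5 members with values on all 4 arrays (26 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it. The median of each list on each array was also ranked among 10000 random lists of the same size, which were not matched on expression.

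The rule for named genes, written before the data were examined, was NFKBIA first, then up to 12 called genes in each direction on the mean with the same sign on every array, up to 6 in each direction on the slope, and for each list up to 4 called members or, where none was called, the 2 members with the largest mean. Where fewer than 5 genes passed, the genes with the largest moderated statistic filled the number to 8 and are said not to pass. At most 2 unnamed probes are given in each direction. List members that passed only when adjusted over the list alone, the probes of NFKBIA and HBA1 are named in addition, chosen after their values were seen.

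The fits were tested on simulated data with the missing values and relative array spreads of these arrays. For the mean over 4 days, with 7713 features, 22% of 50 features changed 1.5-fold were recovered, 68% of 50 changed 2-fold and 96% of 50 changed 3-fold, with 3 false calls. For the day trend, with 6427 features, 4% of 50 slopes of 0.5 log2 per day and 74% of 50 slopes of 1 log2 per day were recovered, with 2 false calls. The simulated features were independent and had no dye bias, and for each comparison all sizes of change were planted together in the same run. More true changes loosen the Benjamini-Hochberg cutoff, so with as few calls as here the recovery may be lower. With correlated genes the number of false calls may differ. Alternatives to the centring, scaling, missing-value filter, probe rule, moderation, day term and size threshold, and the omission of each array in turn, were planned. Array weights, days 3 and 4 alone, days 1 and 2 alone, probes with all 4 values and the estimated correlation were added after seeing the data. Figures were drawn with matplotlib 3.10.9.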

Results

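EJM myeloma cells with an inducible IκBα super-repressor were compared with uninduced cells after 1, 2, 3 and 4 days of 20 µg/ml doxycycline, with 1 array per day. Values were present for 11386 probes on day 1, 10321 on day 2, 13544 on day 3 and 13872 on day 4, out of 15246. The day 1 and day 2 arrays were the more widely spread, with SDs of the log2 ratio over probes of 0.517 and 0.569, against 0.345 on day 3 and 0.380 on day 4. On the day 1 array 123 features were at least 2-fold higher and 174 at least 2-fold lower in induced cells. The corresponding numbers were 161 and 234 on day 2, 53 and 34 on day 3, and 88 and 43 on day 4.

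NFKBIA, the gene for IκBα and the one the transgene is derived from, did not differ from 0 on average. Its mean log2 ratio over 5 probes was -0.14 ± 0.07 (SD, 4 arrays; limma adjusted p = 0.61). The probes disagreed. Of 4 probes with at least 3 values, 2 had a mean below 0 and 2 above, from -0.91 for probe 15866_1 to 0.28 for probe 34886_1. Probe 28424_1 read -0.43 and -0.29 on days 1 and 2, and 0.38 and 0.49 on days 3 and 4. Whether any of these probes detects the transgene is not known here, so this gene does not check the labels.

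**Figure D1:**
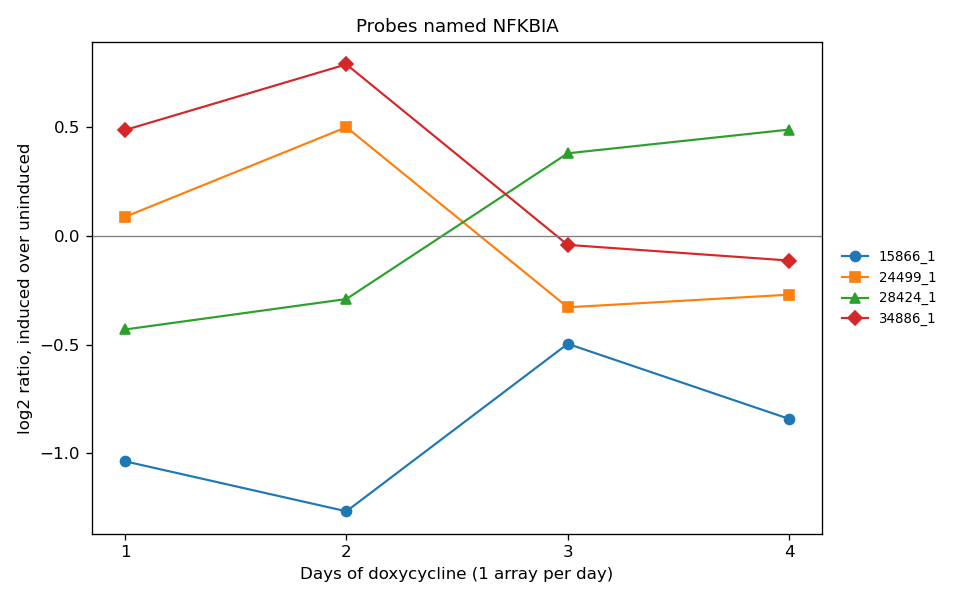
Log2 ratio of induced over uninduced cells (vertical axis) against days of doxycycline (horizontal axis) for the 4 NFKBIA probes with at least 3 values; each point is 1 array, with no error. Probe 15866_1 lay below 0 on every array (mean -0.91), while the others crossed 0.

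The first comparison asked which genes differed between induced and uninduced cells over the 4 days. TNFAIP3 (A20, a deubiquitinase that restrains NF-κB signalling and is itself an NF-κB target) was 2.77-fold lower, with a mean log2 ratio of -1.47 ± 0.28 (SD, 4 arrays; limma adjusted p = 0.0178). All 6 of its probes lay below 0. DPYSL2, a microtubule-binding protein, was lower at -1.17 ± 0.10, UBD (the ubiquitin-like protein FAT10) at -1.11 ± 0.14, and IL2RG (the common gamma chain of cytokine receptors) at -1.05 ± 0.18. ITGB7, the integrin β7 chain, was 2.79-fold higher at 1.48 ± 0.17 (limma adjusted p = 0.00898). The retinol dehydrogenase DHRS9 was higher at 1.33 ± 0.36, the interleukin-5 receptor chain IL5RA at 1.08 ± 0.23, the lysosomal protein cathepsin A (CTSA) at 0.87 ± 0.056 and β-globin (HBB) at 0.85 ± 0.09. Each of these 9 genes had the same sign on all 4 arrays. With arrays scaled to the same spread, or without the day 2, day 3 or day 4 array, 0 of the 9 passed, and 2 passed without the day 1 array.

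In all, 26 features passed the threshold on the mean, 14 lower and 12 higher, of which 9 were named genes (4 lower and 5 higher) and 17 were unnamed probes. The strongest were unnamed: probe 30589_1 had a mean of -2.90 ± 0.21 and probe 15916_1 of -2.46 ± 0.24. Among unnamed probes that were higher, 27516_1 had a mean of 1.17 ± 0.21 and 35199_1 of 1.07 ± 0.22. An unadjusted p under 0.05 was found for 962 features. A limma adjusted p under 0.1 was found for 58 features, 24 lower and 34 higher, the called ones included. The naming rule filled only the lower side, where fewer than 5 genes passed. Among the lower genes that came next and did not pass, ZYG11B had a mean of -0.94 ± 0.31 and the death receptor FAS -0.81 ± 0.26 (limma adjusted p = 0.0728 and 0.0846). The NF-κB subunit RELB had a mean of -0.73 ± 0.21 and the class II chain HLA-DRA -1.09 ± 0.52 (limma adjusted p = 0.094 and 0.109). On the higher side, CD38 had a mean of 0.69 ± 0.09 (limma adjusted p = 0.0741). With the arrays scaled to the same spread 3 features were called, and leaving out an array left 3 to 5. With array weights 291 features were called, and with days 3 and 4 alone 569, all 26 among them in both.

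**Figure D2:**
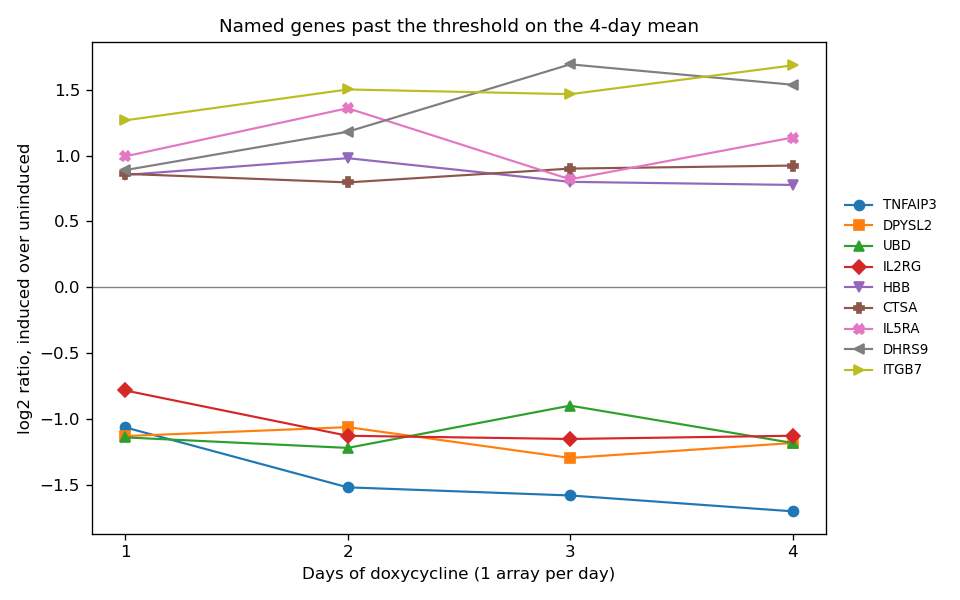
Log2 ratio of induced over uninduced cells (vertical axis) against days of doxycycline (horizontal axis) for the 9 named genes past the threshold on the 4-day mean; each point is 1 array, with no error. The 4 lower genes stayed below 0 and the 5 higher genes above 0 on every array, with means from -1.47 (TNFAIP3) to 1.48 (ITGB7).

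On the mean over the 4 days NF-κB targets were lower as a group, more so on days 1 and 2 than on days 3 and 4. Of 42 measured members 30 had a mean below 0, the median was -0.14, and camera gave an adjusted p of 0.00723 (adjusted p = 0.597 with an estimated correlation). TNFAIP3 was called over all features. Adjusted over the list alone, 4 members were lower and 2 higher: TNFAIP3, FAS, RELB and NFKB2 (-0.88 ± 0.43) were lower, and the chemokine CCL3 (0.69 ± 0.10) and TNFAIP2 (0.69 ± 0.12) were higher. The median was -0.26 on day 1 (percentile 0.19 among random lists), -0.26 on day 2 (0.79), -0.062 on day 3 (4.73) and -0.027 on day 4 (31.57). The median over all features was -0.063, -0.081, 0.006 and 0.002 on days 1 to 4. That of the B cell list was -0.20, -0.21, 0.10 and 0.14 (percentiles 8.44, 8.66, 93.6 and 98.18). A rise from days 1 and 2 to days 3 and 4 was therefore not particular to NF-κB targets. Whether their day 1 and day 2 values depend on signal strength was not tested. The shift of the NF-κB targets did not pass with days 3 and 4 alone (-0.028, adjusted p = 0.349) or without the day 2 array (-0.099, adjusted p = 0.0627). Nor did it pass with the probe with the fewest missing values (-0.068, adjusted p = 0.2), with probes with all 4 values (-0.148, adjusted p = 0.0613) or with array weights (-0.062, adjusted p = 0.0727).

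All 9 measured members of the myeloma NF-κB list had means below 0, with a median of -0.62 and a camera adjusted p of 1.63e-07 (adjusted p = 0.419 with an estimated correlation). This list may have been chosen on arrays like these and is not independent evidence of its direction. It shares members with the NF-κB targets, TNFAIP3, NFKB2 and RELB among them, so these lists are not separate support for each other. TNFAIP3 and IL2RG were called over all features, and adjusted over the list alone 6 members passed: these were TNFAIP3, IL2RG, NFKB2, RELB, CD74 (-0.62 ± 0.34) and WNT10A (-0.38 ± 0.086). The median per day ran from -0.85 on day 2 to -0.47 on day 4. Components of the NF-κB pathway itself did not pass on the mean, with a median of -0.018 over 20 members (adjusted p = 0.887). Their median per day was 0.16 on day 1 (percentile 96.9 among random lists), -0.032 on day 2 (68.2), -0.14 on day 3 (0.88) and -0.14 on day 4 (1.97). None was called over all features, and adjusted over the list alone 1 passed, the TNF receptor TNFRSF1B at -0.54 ± 0.11. TNFRSF17 (BCMA) had a mean of 0.50 ± 0.30.

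MHC class II genes, which present antigen to T helper cells, were lower, with a median of -0.32 over 14 members, 11 of them below 0 (camera adjusted p = 0.000381; adjusted p = 0.419 with an estimated correlation). The median was -0.22 on day 1, -0.56 on day 2, -0.23 on day 3 and -0.18 on day 4. With days 3 and 4 alone the shift was smaller, at -0.19 (camera adjusted p = 0.00367). None passed over all features. Adjusted over the list alone 6 members were lower: HLA-DRA, the invariant chain CD74, HLA-DPA1 (-0.58 ± 0.39), HLA-DQB1 (-0.57 ± 0.11), HLA-DRB1 (-0.47 ± 0.23) and HLA-DQA1 (-0.32 ± 0.08). MHC class I genes did not pass, with a median of 0.04 over 12 members (adjusted p = 0.542), B2M at 0.42 ± 0.11 and PSMB9 at -0.35 ± 0.34.

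Genes of the cell division cycle were lower as groups. All 17 measured S phase genes had means below 0, with a median of -0.36 (camera adjusted p = 2.69e-06; adjusted p = 0.597 with an estimated correlation). The replication licensing genes CDC6 and MCM2 had means of -0.48 ± 0.24 and -0.47 ± 0.24. Of 29 G2/M genes 25 lay below 0, with a median of -0.15 (camera adjusted p = 0.00661; adjusted p = 0.762 with an estimated correlation). The checkpoint genes BUB1B and MAD2L1 had means of -0.42 ± 0.09 and -0.32 ± 0.27. In neither list did a member pass over all features or adjusted over the list alone. With days 1 and 2 alone neither list passed (S phase -0.20, adjusted p = 0.165; G2/M -0.082, adjusted p = 0.88), nor did G2/M without the day 4 array (-0.071, adjusted p = 0.466). Without the day 1 array the G2/M median was -0.269 (adjusted p = 8.33e-07).

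Plasma cell genes were higher, with a median of 0.28 over 16 members, 12 of them above 0 (camera adjusted p = 2.58e-05; adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone 5 members passed, the immunoglobulin joining chain JCHAIN (1.00 ± 0.50, with 1 of its probes at 3.90 on day 1), CD38 (0.69 ± 0.09), SDC1 (0.59 ± 0.44), SSR4 (0.56 ± 0.13) and TNFRSF17. The plasma cell shift did not pass with days 3 and 4 alone (0.034, adjusted p = 0.349). The ER stress list, made up of chaperones and folding enzymes of the endoplasmic reticulum and the sensors of unfolded protein, had a median of 0.42, with 12 of 13 members above 0 (camera adjusted p = 9.02e-07; adjusted p = 0.421 with an estimated correlation). Adjusted over the list alone 7 members passed, PDIA4 (0.82 ± 0.45), HSPA5 (BiP, 0.65 ± 0.29), HSP90B1 (0.65 ± 0.34), ATF6 (0.58 ± 0.16), MANF (0.55 ± 0.17), CALR (0.46 ± 0.16) and EDEM1 (0.42 ± 0.30).

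Adhesion and migration genes had a median of 0.13, with 13 of 22 members above 0 (camera adjusted p = 0.00661; adjusted p = 0.421 with an estimated correlation). ITGB7 was called over all features. Adjusted over the list alone 6 members were higher, ITGB7, LGALS1 (0.56 ± 0.12), PECAM1 (0.52 ± 0.25), CCR1 (0.47 ± 0.31), ITGA6 (0.47 ± 0.11) and CD44 (0.37 ± 0.025), and 2 were lower, the chemokine receptor CXCR4 (-0.65 ± 0.41) and ICAM1 (-0.44 ± 0.27). Ribosomal protein genes had a median of 0.26, with 24 of 25 above 0 (camera adjusted p = 2.72e-08; adjusted p = 0.494 with an estimated correlation). RPS4X, at 0.64 ± 0.15, passed adjusted over the list alone. Genes of the respiratory chain had a median of 0.19, with 12 of 15 above 0 (camera adjusted p = 0.00087; adjusted p = 0.597 with an estimated correlation). UQCRB, at 0.55 ± 0.07, passed adjusted over the list alone. The shift of the respiratory chain did not pass without the day 2 array (0.097, adjusted p = 0.0627), with array weights (0.12, adjusted p = 0.218) or with days 3 and 4 alone (0.026, adjusted p = 0.692). That of the adhesion and migration genes did not pass with the probe with the fewest missing values (0.014, adjusted p = 0.0834), with array weights (0.074, adjusted p = 0.113) or with days 3 and 4 alone (0.097, adjusted p = 0.298).

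**Figure D3:**
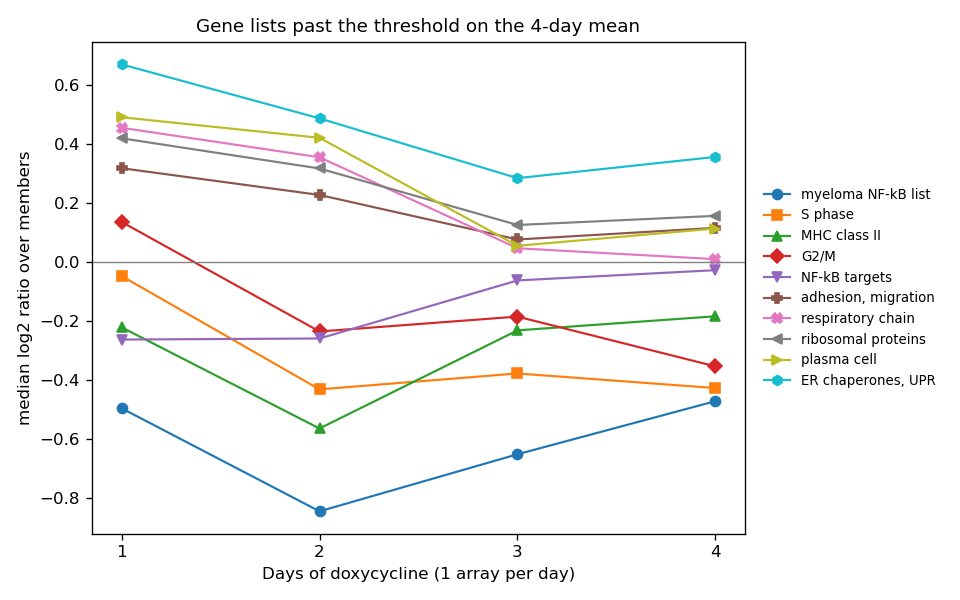
Median log2 ratio of induced over uninduced cells over the members of a list (vertical axis) against days of doxycycline (horizontal axis) for the 10 lists past the threshold on the 4-day mean; each point is the median on 1 array, with no error. The myeloma NF-κB list was the lowest on all 4 days and the ER stress list (ER chaperones, UPR in the key) the highest, at 0.67 on day 1 and 0.36 on day 4.

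The other lists did not pass on the mean. B cell genes had a median of -0.06 (adjusted p = 0.808), with ID3 at -0.51 ± 1.55 and CD79B at 0.45 ± 0.22. The ID3 mean rests on probe 17817_1, which read -5.63 on day 2 and between -0.251 and 0.057 on the other days. Interferon response genes had a median of 0.03 (adjusted p = 0.542), with IFI44 at 0.65 ± 1.07 and SP110 at -0.46 ± 0.15. Inhibitors of apoptosis had a median of -0.04 (adjusted p = 0.849), with BAG1 at 0.33 ± 0.25 and BAG3 at 0.32 ± 0.31. Promoters of apoptosis had a median of -0.03 (adjusted p = 0.808) and p53 targets of -0.0125 (adjusted p = 0.887). FAS passed adjusted over each of these lists alone, CASP10 had a mean of 0.38 ± 0.16 and CCNG1 of 0.33 ± 0.10. The ATF4 amino acid response had a median of 0.0085 (adjusted p = 0.849), with CEBPB at -0.30 ± 0.23 and ATF3 at -0.29 ± 0.43. It was called lower without the day 1 array (-0.198, adjusted p = 0.0167) and with days 3 and 4 alone (-0.173, adjusted p = 0.0116). MYC targets had a median of 0.10 (adjusted p = 0.0732), with CAD at 0.49 ± 0.69 and PPAN at 0.26 ± 0.15. STAT3 targets had a median of -0.15 (adjusted p = 0.542), with ICAM1 at -0.44 ± 0.27 and IL10 at -0.33 ± 0.53. Sterol synthesis genes had a median of 0.04 (adjusted p = 0.78), with SQLE at 0.31 ± 0.22 and FDPS at -0.18 ± 0.30. Glycolysis and hypoxia genes had a median of 0.05 (adjusted p = 0.743), with GAPDH at 0.40 ± 0.29 and ADM at -0.36 ± 0.16. Mitochondrial ribosomal protein genes had a median of -0.03 (adjusted p = 0.743), with MRPS10 at 0.60 ± 1.00 and MRPS15 at 0.28 ± 0.05. Proteasome genes had a median of -0.08 (adjusted p = 0.808), with PSMB7 at -0.35 ± 0.10. Only 4 heat shock genes were measured on enough arrays, with a median of 0.06 and no list test, and BAG3 and HSP90AA1 (0.08 ± 0.31) were its largest means.

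Of the markers of other cell types, the T cell list and the list of red cell and stromal markers did not pass. T cell markers had a median of 0.0011 over 14 genes (camera adjusted p = 0.607), with PRF1 at -0.48 ± 0.33 (3 arrays) and CD5 at -0.42 ± 0.22. The list of red cell and stromal markers had a median of -0.14 over 9 genes (camera adjusted p = 0.808). HBB, described above, is a member of it. Myeloid markers numbered 6, with a median of -0.08 and no list test, and CD14 had a mean of 0.37 ± 0.46 and AIF1 of -0.28 ± 0.30 (3 arrays). Median and test differed in sign for the inhibitors of apoptosis, the p53 targets, the ATF4 response, the mitochondrial ribosomal proteins, and the red cell and stromal markers, none of which passed.

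In total 10 of 26 lists passed on the mean, 5 lower and 5 higher, and with an estimated correlation 0 did (smallest adjusted p = 0.419, with 2 lists at an unadjusted p under 0.05), as with fry (0 lists).

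The second comparison asked which genes changed over the 4 days of induction. Any difference in time in culture from the control cannot be told apart from induction in these slopes. No feature passed on the slope (0 of 6427 with limma, smallest adjusted p = 0.304), while 963 had an unadjusted p under 0.05, 368 with a negative and 595 with a positive slope. The genes with the largest moderated statistics, none of which passed, included the mitotic survival gene BIRC5, with a slope of -0.51 ± 0.10 log2 per day (SE, 4 arrays) and values from 0.89 on day 1 to -0.64 on day 4. Others with negative slopes were CLOCK (-0.54), SLC39A14 (-0.39), TUBA1A (-0.37), UBE2S (-0.44), ELP2 (-0.39), PDHA1 (-0.35) and PCOLCE2 (-0.39). Positive slopes were those of GZMA (0.71), LAMA2 (0.63), HNRNPA2B1 (0.47), RBBP5 (0.48), ISL1 (0.47), RNF144A (0.56), HOXB7 (0.42) and MSX2 (0.44). The standard errors of these slopes ran from 0.081 (PDHA1) to 0.109 (RNF144A). The probes of GZMA, LAMA2 and HNRNPA2B1 differed in the sign of their means. For GZMA only probe 17223_1 had values on all 4 days, at -1.357, -0.57, 0.096 and -0.038 on days 1 to 4. Probes 28390_1 (0.989) and 28932_1 (1.395) entered its day 4 average and had no day 1 value. The GZMA slope therefore rests in part on which probes had values. Adjusted over the list alone, 3 slopes passed in the 28 lists: GZMA among the T cell markers, and HSP90AA1 (-0.24) and HSPA1A (-0.25) among the heat shock genes.

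As groups, 9 lists fell over the days and 1 rose at the preset correlation, and 0 of these 10 held with an estimated one (adjusted p = 0.542 with an estimated correlation for each). G2/M genes fell, with 24 of 28 slopes below 0, a median slope of -0.16 log2 per day and a camera adjusted p of 4.46e-05 (adjusted p = 0.542 with an estimated correlation). Their median was 0.14 on day 1 and -0.35 on day 4. Falls were also found for S phase genes (15 of 17 slopes below 0, adjusted p = 0.00217), the ATF4 amino acid response (11 of 12, adjusted p = 0.000629), MYC targets (10 of 11, adjusted p = 0.00357), plasma cell genes (12 of 15, adjusted p = 0.00217), ER stress genes (10 of 13, adjusted p = 0.031), glycolysis and hypoxia genes (16 of 19, adjusted p = 0.0031), ribosomal proteins (19 of 23, adjusted p = 0.00883) and the respiratory chain (11 of 13, adjusted p = 0.00217), each with an adjusted p = 0.542 with an estimated correlation. B cell genes rose, with 17 of 19 slopes above 0 (adjusted p = 0.0187; adjusted p = 0.542 with an estimated correlation), from a median of -0.20 on day 1 to 0.14 on day 4. The falls of the ER stress genes and the ribosomal proteins did not pass with arrays scaled to the same spread (adjusted p = 0.365 and 0.19). Nor did they with the probe with the fewest missing values (0.133 for both) or with probes with all 4 values (0.0584 and 0.0581). Without the day 1 array 3 lists passed, plasma cell, glycolysis and hypoxia, and respiratory chain genes, and the median slope was then -0.079 for G2/M (adjusted p = 0.228) and 0.0125 for S phase genes. The rise of the B cell genes did not pass without the day 4 array (adjusted p = 0.0785), with the probe with the fewest missing values (0.154) or with probes with all 4 values (0.0524). With fry 1 list passed. The NF-κB targets did not pass on the slope (median 0.10 log2 per day, adjusted p = 0.162), nor did the myeloma NF-κB list (0.15, adjusted p = 0.698), the NF-κB pathway components (-0.11, adjusted p = 0.0811) or MHC class II (-0.0062, adjusted p = 0.696). With each probe tested on its own the median slope of the myeloma NF-κB list was -0.084 and passed (camera adjusted p = 0.0429). That setting counts each probe as a member, so genes with many probes, such as CD74 and TNFAIP3, weigh more. Probes of the same gene are not independent, so this p-value is too small.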

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

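The tests of hemoglobin and of a constant dye bias were chosen after the results were seen. Among 98 named genes and list medians with values on all 4 days, 7 had 1 day far from the other 3. Chance gives about 1 in 20 such cases for normally spread items not chosen on their values. Many of these genes were chosen for a large mean, which a single extreme day can give, so that rate does not apply to them. Of the 7, 4 lay on day 1. IL2RG was -0.78 on day 1 and between -1.15 and -1.13 on the other days, and TNFRSF1B was -0.69 on day 3 and between -0.51 and -0.47 otherwise. JCHAIN stood at 1.75 on day 1 (0.73 to 0.79 otherwise), RPS15A at 2.03 on day 4 (-0.16 to 0.12) and MRPS10 at 2.09 on day 1 (-0.0065 to 0.19). The median of the MHC class II list was -0.56 on day 2 (-0.23 to -0.18 otherwise), and that of the S phase list was -0.047 on day 1 (-0.43 to -0.38 otherwise). Some of these values rest on single probes. For JCHAIN on day 1, probe 23859_1 read 3.90 while probes 19370_1 and 34350_1 read 0.88 and 0.48. The MRPS10 value on day 1 is that of probe 34674_1 alone, with the other probe missing, and RPS15A has 1 probe.

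The 9 lists that fell over the days include several of abundant transcripts, such as ribosomal proteins and the respiratory chain. A dependence of the day 1 and day 2 log ratios on signal strength could give such falls. It could also add to the rises of these lists on the mean. The ribosomal protein median was 0.42, 0.32, 0.13 and 0.16 on days 1 to 4, and that of the respiratory chain 0.46, 0.36, 0.047 and 0.01. It could likewise give the rise of the B cell genes over the days if their spots were dim, which is unknown here. Features with a value on all 4 arrays, a stand-in for bright spots, lay above features missing on another array by 0.119 on day 1 (bootstrap SE 0.0177) and by 0.014 on day 2 (SE 0.0297), with 0.0605 on day 3 and 0.038 on day 4, as medians of log2 ratios. Over single probes, computed first, the gaps were 0.134 on day 1 and 0.039 on day 2 (SE 0.0137 and 0.0192). The day 2 gap lies below the 0.05 set in advance as the bound against this explanation by more than its SE over features, the level set in advance, but by less than its SE over single probes. At both levels it lies more than 2 SE below the 0.1 that the explanation needs on both days. Day 2 had the most missing values, so a feature with a value there had already passed where many others did not. Only 548 features measured on day 2 were missing on another array, against 2402 on day 3 and 2543 on day 4. Without intensities it is unknown whether those 548 were dimmer, so the day 2 gap cannot decide. A dependence on the day 1 array, alone or with the day 2 array, stays open, and without the day 1 array 3 lists passed. No biological explanation was tested.

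The fall of the 9 measured genes of the myeloma NF-κB list could be given by a constant dye bias of each gene, since Cy5 was always the induced sample. Such a bias predicts no difference between days 3 and 4 and days 1 and 2, as does a steady effect of induction. The mean difference over the 9 genes was 0.196 (SE 0.154), which decides neither way. That SE is over genes that share the same 4 arrays. Single genes moved both ways, such as TNFAIP3 (-1.29 to -1.64) and RELB (-0.89 to -0.56), so the average can hide changes. The super-repressor, the dye, doxycycline itself and any difference in time in culture cannot be told apart in the mean with this design.

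HBB was higher on all 4 days (0.85 ± 0.091, SD, 4 arrays). Red cell RNA in the induced samples would raise HBA1 about as much. HBA1 minus HBB was -0.99 (SE 0.176) on average, with HBA1 at -0.14 ± 0.42. HBA1 probe 24843_1 had a value on day 4 only, and 27097_1 ran from -0.79 on day 1 to 0.98 on day 2. The difference argues against red cell RNA as the source only if these probes detect HBA1, which is not known here. The induced samples are labelled as EJM, an established cell line, with no source of red cells named. A dye bias of the HBB probes, cross-hybridisation and a change of HBB in these cells stay open and were not tested.

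Reversing the sign of single arrays or reordering the days gives too few arrangements for a share under 0.05. Of 8 sign assignments, 1 (the real one) gave as many as 26 features, with at most 0 in the others. For the 10 lists on the mean 2 assignments gave as many, the real one and that with day 4 reversed. Reversing days 3 and 4 together still left 9 lists, and reversing day 3 alone left 8. Assignments with day 2 reversed against day 1 gave 1 to 5 lists. The count of 10 lists therefore does not set the real signs of the day 3 and day 4 arrays apart. Of 12 orders of the days, 12 gave at least the real 0 features on the slope (highest other 0), and 2 gave 10 lists, the real order and another (highest other 10).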

How the results depend on the processing

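Array weights, days 3 and 4 alone, days 1 and 2 alone, probes with all 4 values and the estimated correlation were chosen after seeing the data, array weights after their count of calls had been printed. Of 26 features called on the mean, 3 remained with arrays scaled to the same spread and 1 with days 1 and 2 alone. The count was 42 when all 4 arrays were needed and 55 with each probe tested on its own (fewer or other features tested), 291 with array weights and 569 with days 3 and 4 alone, each holding all 26. Leaving out an array in turn gave 3 to 5. The day 3 and day 4 arrays had weights of 3.02 and 1.80, against 0.408 and 0.450 for days 1 and 2. All 4 arrays have the same dye orientation, so a constant dye bias would be called with days 3 and 4 too. The other settings gave 22 to 33. No feature was called on the slope under any alternative run. Of the 9 called named genes, 0 passed with scaled arrays or without the day 2, 3 or 4 array, 2 without day 1, 4 with the probe with the fewest missing values and 7 with day as a covariate, and 0 of 99 values reversed. Lists called on the mean numbered 1 with a size threshold of 1.5-fold, 0 with an estimated correlation and 8 to 11 when an array was left out. On the slope they numbered 0 with a size threshold, 0 with an estimated correlation and 3 to 11 when an array was left out, 3 of them without day 1. The NF-κB target shift of -0.14 was -0.068 with the probe with the fewest missing values (adjusted p = 0.2), -0.148 with probes with all 4 values (0.0613), -0.0615 with array weights (0.0727), -0.0279 with days 3 and 4 alone (0.349) and -0.142 with an estimated correlation (0.597), and it ran from -0.208 to -0.0849 when an array was left out, past the threshold except without day 2. It kept its direction and call in 8 of 14 alternatives, and the myeloma NF-κB list in 13 of 14. The other lists called on the mean did so in 10 (adhesion and migration, respiratory chain) to 13 of 14, and those called on the slope in 7 (B cell, ER stress, ribosomal proteins) to 11 of 12. Directions reversed for the slope of the myeloma NF-κB list with single probes (-0.084, adjusted p = 0.0429) and for the slope of the S phase list when an array was left out (-0.153 to 0.0125). With single probes, repeated probes of a gene count as separate list members. The median of the ATF4 list over the 4-day means ran from -0.198 to 0.0906 when an array was left out. It turned below 0 and the list was called lower without day 1 (-0.198, adjusted p = 0.0167) and with days 3 and 4 alone (-0.173, adjusted p = 0.0116). It was also below 0, without a call, with scaled arrays (-0.035), single probes (-0.019), the probe with the fewest missing values (-0.015) and array weights (-0.125). Its list test pointed down in the fit of all 4 arrays too (adjusted p = 0.849). The cause was not tested. A further 81 values that passed in neither fit changed sign, 79 of them of gene lists. They were first counted as reversals, and were set apart only after this number was seen. The filter on low signal was not run, since no intensities were used here. The mean log2 ratio against 0 is already a paired comparison, since each array holds both conditions. With 1 group no other pairing was possible. Without intensities, what signal over background limits is unknown.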

Other observations

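With array weights, a setting chosen after seeing the data, limma called 145 features lower and 146 higher, and the genes given here were chosen from them after their values were seen, with no test of any group. Among genes not described above, osteopontin (SPP1) had a weighted mean log2 ratio of 1.73 (adjusted p = 0.0136), and the endoplasmic reticulum translocon and signal peptidase subunits SSR3 and SPCS3 of 1.23 and 0.86 (adjusted p = 0.0382 and 0.00703). The lysosomal protease CTSB, the tetraspanin CD63 and the lysosomal lipase LIPA were higher at 0.78, 0.81 and 0.53, and the ferritin light chain FTL and the metallothionein MT2A at 0.76 and 0.55 (adjusted p from 0.00457 for CTSB to 0.0228 for LIPA). The GTPase RAP2A was lower at -0.95, the condensin subunit NCAPG2 at -0.88, the cell cycle transcription factor MYBL2 at -0.68, the helicase subunit MCM7 at -0.68 and the checkpoint ligand CD274 (PD-L1) at -0.56 (adjusted p from 0.00641 for RAP2A to 0.047 for MYBL2). These calls rest mainly on the day 3 and day 4 arrays, which carry weights of 3.02 and 1.80, and a constant dye bias remains in them.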
